A study of Rhodopseudomonas palustris with 4 samples.

How the data were processed

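The data are RNA-seq measurements from 4 samples of Rhodopseudomonas palustris, 2 of the parent strain CGA753 (samples 1 and 2, labelled as wild-type control) and 2 of a suppressor mutant of a fixC deletion strain (samples 3 and 4). Per the labels' protocols, total RNA was treated with DNase, ribosomal RNA was depleted with a Ribo-Zero kit, and libraries were made with an NEBNext Ultra kit. Groups were taken from the sample titles. Per the submitters' processing notes, FastQC, Trim Galore 0.6.2, DESeq2 and R 3.6 were used, with no role given for each. The aligner, the counting program, the use of strand in counting and the handling of reads that fit several genes are not given in the sources used here.

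The deposited table gives for each of 2990 genes a start, an end, a strand and 1 value per sample. Coordinates are printed as in that table, on the chromosome record of strain CGA009 that it names. Gene symbols were taken from the table too, which gives 835 genes a symbol of their own. The other 2155 are named by locus tag. The reference gene table at hand is of another strain and matched 0 of the locus tags, so it was not used for names or positions. Locus tags reach RPA4836, and 1848 numbers up to that tag have no gene in the table and were not analysed here.

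Per the file headers, the values are RPKM, but the deposited values behave as estimated counts and were treated as such. Multiplied by gene length in kilobases they sum, in units of 1e+06, to 19.3, 26.8, 26.9 and 24.2 in samples 1 to 4, where RPKM cannot exceed 1. Between 653 pairs of neighbouring genes on 1 strand, the slope of log2 value on log2 gene length was 0.96, 0.98, 0.91 and 0.92 (SE 0.04 to 0.05), near 1, as for counts without division by length. Most values are not whole, and 9 genes hold a whole value in at least 1 sample (tolerance 1e-06). If the authors had divided by length after all, the fold change of a gene would be nearly the same but its weight in the library total would not, so the values multiplied by length were tried as an alternative. Median counts per gene were 1487.5, 2045, 1885 and 1686.

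No gene of the table has a log2 fold change between -0.188 and 0.077, the strains overlap in 0 genes, and the empty range is wider among genes with low counts. No header or label records a step that would explain this. Each gene's values stand as they are, but the share of genes called, adjusted p-values, list tests and the scaling between libraries hold for these genes alone, and CPM here means a share of the table's counts.

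Values were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with its defaults, which removed no gene, TMM scaling, and the quasi-likelihood test of suppressor against parent with no covariate, with Benjamini-Hochberg adjustment at 0.05 over 2990 genes. The biological coefficient of variation was 0.068. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of the test's F value, with a median of 0.08. Of 30 gene lists defined by symbol, locus range or product name, 6 had no member, because the table holds no product names, 3 had 1 or 2 members and 21 had at least 3. Symbols were matched with their case, so a symbol that opens with a capital letter (NifD1, NifD2, CbiG) entered no list. Those 21 were tested with fry on log2 CPM with a prior count of 1 (limma 3.58.1) and Benjamini-Hochberg adjustment over the lists. The null of fry is that no gene of a list differs, whereas here every gene separates the strains. fry asks whether the genes of a list move, on balance, one way and does not compare them with other genes. camera, which does, was run with a preset correlation of 0.01 and with an estimated correlation.

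The design, the lists, the alternatives and the rule for named genes were set before the data were examined, with the edgeR test as the choice for counts. The rule named fixA, fixB, fixC, fixX, nifH, nifD, nifK and nifA, the 12 largest rises and the 12 largest falls among genes called with a mean of at least 10 CPM and no overlap between the strains, up to 3 called members of each list with the largest change and its most abundant member (by mean CPM over all 4 libraries), the most abundant gene that is not a stable RNA, and ferredoxin and flavodoxin genes. Names from lists that did not pass were given in part. Further members of lists (metG, pucAb, pucAe, pucBe, pucC, pucAd, pucBc, pucBd, nifS2, nifV), NifD1, NifD2, ferredoxin and Fld genes by symbol and 5 chromosome stretches were chosen after the values were seen.

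Alternatives were DESeq2 1.42.0, limma-voom, limma-trend on log2 values with pseudocounts of 0.1, 1 and 10, RLE and upper-quartile scaling, library totals, no filter or at least 10 CPM in 2 samples, stable RNAs or the 10 most abundant genes left out, stricter thresholds, and each library left out in turn. Chosen after the data had been seen were a scaling that puts the middle of the empty range at 0, values multiplied by gene length, values divided by 2, and the 5 stretches left out. The fit was tested on simulated counts for the 2990 genes with 200 genes changed. All of them were recovered at log2 changes of 0.5 (67 of 67), 1 (67 of 67) and 2 (66 of 66), with 10 false calls among 210. Most simulated genes were unchanged, whereas every gene of the table separates the strains, so these rates do not carry over to its calls. With 1 simulated list of 20 genes shifted by a log2 of 1, fry and both forms of camera found it and called 0 of 20 lists without a shift. Simulated genes varied independently and genes outside the shifted list were unchanged. The lists of the table differ in both respects, so this result does not carry over to them. Figures and summaries were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.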

Results

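RNA was sequenced from Rhodopseudomonas palustris, a purple phototrophic bacterium that fixes nitrogen, in 2 strains. The parent was CGA753 (libraries 1 and 2), and the other strain was a suppressor mutant that arose from a CGA753 derivative with a deletion of fixC (libraries 3 and 4). Cells were taken from 10 mL cultures in minimal medium without ammonium sulfate, with 20 mM acetate, at an optical density of 0.45 to 0.47. The table used here held 2990 genes and summed to 16937011 and 23092066 counts in the parent libraries and to 20946587 and 18819655 in the suppressor libraries. These sums cover the genes of the table and are not the full sequencing depth, so every CPM value is a share of this table (per 1e+06 of its counts). The labels do not say that the libraries of a strain came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Across genes, Pearson's r of log2 counts was 0.995 between the parent libraries, 0.998 between the suppressor libraries, and 0.866 to 0.882 between strains (genes are not independent replicates). Both pairs differed by more than sampling noise, with a chi-square per degree of freedom of 72.1 for the parents and 4.0 for the suppressors, and each library counted as 1 sample.

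The comparison of the strains bears on how a cell that has lost FixC can still supply nitrogenase with electrons. However, no library came from the fixC deletion strain before suppression. Each change may therefore stem from the loss of fixC, from the suppressor mutation or from both. FixABCX is a flavoprotein complex that passes electrons from NADH to a low-potential acceptor such as ferredoxin, from which nitrogenase draws. The deleted gene was examined first. fixC (RPA4603, chromosome positions 5188370 to 5189677, minus strand) held 61632 and 77863 counts in parent libraries 1 and 2 and 14 and 92 counts in suppressor libraries 3 and 4. The suppressor libraries thus kept 0.019% and 0.139% of the mean parent CPM, which goes with the labels of all 4 libraries. Its log2 fold change was -10.35 ± 0.54 (SE, n = 2 per strain; adjusted p = 5.25e-06, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The size depended on the few remaining counts, and was -9.49 without suppressor 3 and -12.35 without suppressor 4.

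The other fix genes of the locus were still expressed and moved in both directions. fixX rose from 817 ± 41.1 to 1334 ± 22.1 CPM (SD, n = 2; log2 0.71 ± 0.07 SE) and fixB from 1882 ± 69.4 to 2680 ± 68.8 CPM (log2 0.51 ± 0.07). fixA, at the other end of the locus, fell from 471 ± 85.1 to 315 ± 0.344 CPM (log2 -0.58 ± 0.12), a change of -0.38 without parent 1. nifA, which encodes the transcriptional activator of the nif genes, rose from 1725 ± 46.1 to 4515 ± 13.1 CPM (log2 1.39 ± 0.07). For these 4 genes the adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was at most 0.00342. The structural genes nifH, nifD and nifK of the molybdenum nitrogenase were not analysed here.

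Within the nif cluster (RPA4602 to RPA4633), 26 of 32 locus tags were in the table, of which 19 rose, 6 fell and 1 did not pass (edgeR quasi-likelihood test, Benjamini-Hochberg), with a median log2 fold change of 0.54. The falls include the deleted fixC, without which 5 fell and the median was 0.56. nifS2, a cysteine desulfurase gene, rose by 1.18 ± 0.12 on the log2 scale, and nifV, the homocitrate synthase gene, by 1.06 ± 0.08. nifE, which serves cofactor assembly and had the highest mean of the list over all 4 libraries (fixC was higher in the parent and nifA in the suppressor), rose from 2696 ± 172 to 3641 ± 6.52 CPM (log2 0.43 ± 0.07). Of the 7 further genes that the list takes in by symbol, 1 rose and 6 fell, with a median of -2.89. NifD1 (-3.72 ± 0.14) and NifD2 (-3.43 ± 0.13), whose capital letter kept them out of the list, fell as well. The whole list of 33 genes had a positive median of 0.43 and a negative mean of -0.55, and the rotation test fry did not pass for it (direction down, adjusted p = 0.893). This list held the deleted fixC, whose fall the genotype fixes, and the genes by symbol from elsewhere, most of which fell. Among the latter, nifH1, nifB2, nifH2, nifB1 and nifH3 lie in the stretches of large falls described below. A downward direction of the list therefore does not describe the cluster. Adjusted over the list alone, the same 20 rises and 12 falls were counted, and without parent 2 the fry test passed in the downward direction (adjusted p = 0.032). Among ferredoxin genes, which were picked by symbol after the data had been seen, ferN rose (log2 0.48 ± 0.07), while fer1 (-0.54 ± 0.13), fdxB (-0.46 ± 0.14) and the ferredoxin reductase gene fpr (-1.36 ± 0.08) fell. Without parent 1 the changes of fer1 and fdxB were -0.32 and -0.22, and fdxB no longer passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment without suppressor 3 (adjusted p = 0.0738) or without suppressor 4 (adjusted p = 0.0504). FldA (RPA4696, 1859 ± 71.9 to 1470 ± 35.2 CPM, SD, n = 2; -0.34 ± 0.07 SE) and FldZ (RPA4698; -0.68 ± 0.22) fell too. FldA is the symbol of a flavodoxin, but this gene of 1119 bp is long for one. Without product names, its function and that of FldZ are uncertain here, so they do not show that flavodoxin fell. Carriers among the 2155 genes without a symbol, which include 11 of the 12 largest rises, could not be recognised, so these 6 genes do not show how electron carriers changed as a group. Its call ended in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment without suppressor 3 (adjusted p = 0.101) and without suppressor 4 (adjusted p = 0.0695), and that of FldZ ended without suppressor 3 (adjusted p = 0.0611) and without parent 2 (-0.30, adjusted p = 0.0947).

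**Figure D1:**
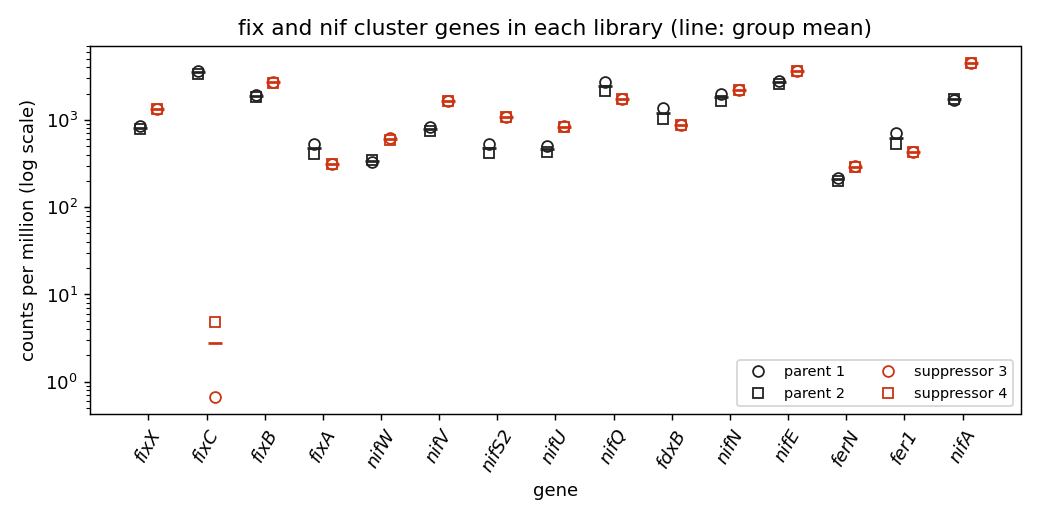
CPM (log scale) of 15 genes of the fix and nif cluster in each of the 4 libraries, with parent in black, suppressor in red and a line at each group mean. fixC drops from 3656 and 3368 in the parent to 0.67 and 4.89 in the suppressor, while nifA rises from a mean of 1725 to 4515.

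Across the table, 2862 of 2990 genes passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, 1407 with higher and 1455 with lower expression in the suppressor, and 128 did not pass. At least a 2-fold change was seen in 343 genes that rose and 338 that fell, and at least an 8-fold change in 23 and 30. The most abundant gene, RPA2419, fell from 46749 ± 1209 to 26272 ± 49.2 CPM (SD, n = 2; log2 -0.83 ± 0.07 SE). The libraries of the strains did not overlap in any of the 2990 genes, where chance gives 33.3%, and no gene had a log2 fold change between -0.188 and 0.077. Genes with smaller differences were therefore not analysed here, and the counts and the adjusted p-values describe a set in which every gene separates the strains. In such a set the null of fry, that no gene of a list differs, is false for any list. A fry call below thus tells only which direction prevailed in a list. With 2 libraries per strain, a permutation of the labels cannot give a two-sided p below 0.33.

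**Figure D2:**
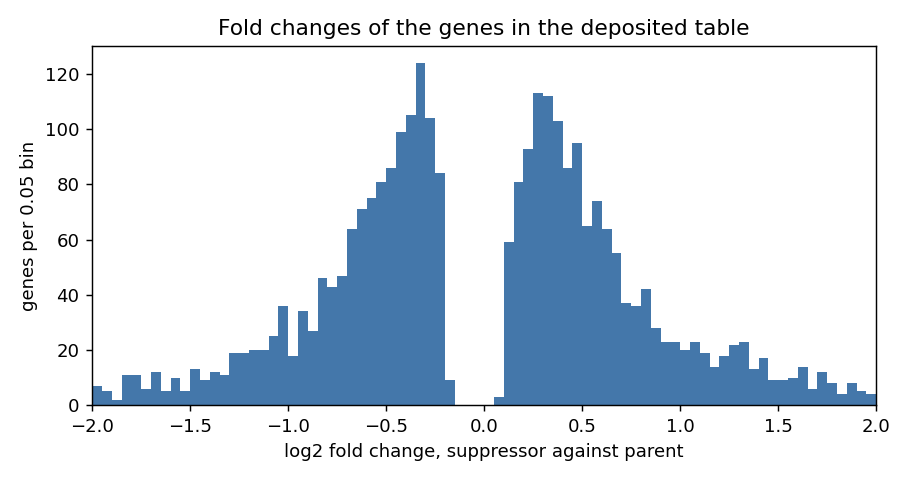
Number of genes per 0.05-wide bin of log2 fold change (suppressor against parent), drawn from -2 to 2, with 165 genes lying outside. No gene falls between -0.188 and 0.077.

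The 12 largest rises, among genes with a mean of at least 10 CPM, came from 3 stretches of the chromosome, and 11 of them have no gene symbol in the file. RPA2124 rose from 1145 ± 144 to 18678 ± 327 CPM (SD, n = 2; log2 4.03 ± 0.11 SE). With it, in tags RPA2114 to RPA2129 (positions 2378795 to 2392511), rose RPA2117 (log2 4.51 ± 0.16), RPA2116 (4.38 ± 0.13), RPA2122 (3.73 ± 0.10) and cynS, a cyanate hydratase gene (3.75 ± 0.11). In RPA2376 to RPA2395 (positions 2692943 to 2715154) the same rule picked RPA2390 (from 398 to 6934 CPM; log2 4.12 ± 0.13), RPA2389 (3.68 ± 0.12), RPA2386 (3.64 ± 0.14), RPA2388 (3.62 ± 0.10), RPA2387 (307 ± 59.9 to 3728 ± 107 CPM) and RPA2385 (3.54 ± 0.17). RPA2307, in RPA2306 to RPA2313, rose by 3.77 ± 0.08. For all 12 genes the adjusted p was at most 3.47e-06 (edgeR quasi-likelihood test, Benjamini-Hochberg).

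Of the 12 largest falls, 1 was fixC and 8 lay in RPA2346 to RPA2364 (positions 2658270 to 2680643). There nifH1, a gene with the symbol of the nitrogenase iron protein, fell from 881 ± 203 to 34.7 ± 0.857 CPM (SD, n = 2; log2 -4.67 ± 0.17 SE), and its neighbour nifB2 fell from 246 to 12.7 CPM (-4.28 ± 0.13). Around them fell RPA2352 (log2 -4.75 ± 0.20), RPA2361 (-4.71 ± 0.17), RPA2362 (-4.18 ± 0.18), RPA2360 (-4.16 ± 0.11), RPA2359 (-3.95 ± 0.12) and RPA2355 (-3.75 ± 0.11). A second stretch, RPA2608 to RPA2636 (positions 2966741 to 3000286), held RPA2626 (-4.04 ± 0.18) and nifH3 (-3.74 ± 0.19). RPA1958 stood alone (-3.84 ± 0.07). The adjusted p was at most 5.25e-06 for all 12 (edgeR quasi-likelihood test, Benjamini-Hochberg).

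**Figure D3:**
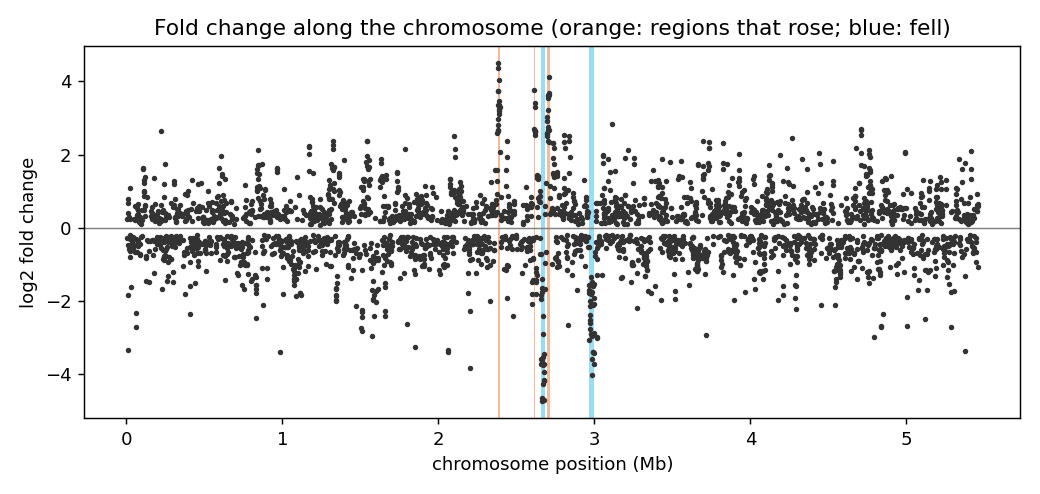
Log2 fold change (suppressor against parent) of each gene of the table except fixC, against its start on the chromosome in Mb. Orange bands mark the 3 stretches that held the 12 largest rises and blue bands the 2 stretches that held 10 of the 12 largest falls.

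Genes of sulfur supply, of the NADH dehydrogenase and of the uptake hydrogenase were lower in the suppressor. Of 23 genes of sulfur assimilation and methionine synthesis, 22 fell and 1 rose, with a median log2 fold change of -1.35. sbp, for the periplasmic sulfate-binding protein, fell from 1180 ± 147 to 215 ± 7.59 CPM (SD, n = 2; log2 -2.46 ± 0.10 SE), as did metH, for methionine synthase (-1.98 ± 0.07), and cysD, for a subunit of sulfate adenylyltransferase (-1.78 ± 0.10). metK, for S-adenosylmethionine synthetase and the most abundant of the list, fell from 3884 to 1266 CPM, and the gene that rose was metG (0.40 ± 0.06), for methionyl-tRNA synthetase. All 19 nuo genes of the NADH dehydrogenase that were in the table fell, with a median of -0.93, among them nuoM1 (-1.32 ± 0.07), nuoN1 (-1.32 ± 0.08), the low-abundance nuoL3 (-1.59 ± 0.23) and the most abundant, nuoG1 (548 to 287 CPM; -0.93 ± 0.07). Of the 21 tags in the locus range of the hydrogenase, 11 had no gene in the table. In the hydrogenase list 11 of 12 fell and 1 rose, with a median of -1.16, led by the weakly expressed hupJ (6.66 to 2.24 CPM; -1.57 ± 0.23), hupK (-1.46 ± 0.13) and hypA (-1.41 ± 0.27). Its most abundant member, hupA (-0.31 ± 0.08), bears a symbol that is also used for the DNA-binding protein HU, and no longer passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment without suppressor 3 (adjusted p = 0.101) or suppressor 4 (adjusted p = 0.14). This hupA (RPA2953) is 312 bp long and lies beside nuoA1 (RPA2952), away from the hup and hyp genes at RPA0968 to RPA0978. It may therefore not be a hydrogenase gene, although it is counted in the list. Adjusted over the list alone, each of these lists had the same counts. Each list moved down by fry (Benjamini-Hochberg adjusted p = 0.00607), but adjusted p = 0.566 with an estimated correlation in camera, 0.129 to 0.135 by fry without suppressor 3 and 0.13 without suppressor 4.

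The genes for the peripheral light-harvesting complex, LH2, divided by locus. pucBa fell from 16269 ± 3695 to 1999 ± 97.8 CPM (SD, n = 2; log2 -3.02 ± 0.16 SE), and pucAa (-2.98 ± 0.11), pucBb (-2.73 ± 0.10), pucAb (-2.69 ± 0.09), pucAe (-2.42 ± 0.07), pucBe (-2.27 ± 0.10) and pucC (-1.62 ± 0.07) fell too. pucBd (1.14 ± 0.08), pucAd (1.12 ± 0.07) and pucBc (0.61 ± 0.08) rose. In all, 7 of 10 puc genes fell and 3 rose, also when adjusted over the list alone, with a median of -2.35 (fry, direction down, adjusted p = 0.00607, but adjusted p = 0.697 with an estimated correlation). Without suppressor 3 or suppressor 4 the fry adjusted p was 0.135 or 0.13. The puc copies are close relatives, and how reads that fit more than 1 copy were counted is not given in the sources used here, so their separate levels are uncertain. The photosynthesis gene cluster, with reaction centre, core antenna and pigment genes, gave 9 rises, 18 falls and 4 genes that did not pass (8 rises and 18 falls adjusted over the list alone), with a median of -0.32, and did not pass fry (adjusted p = 0.1), although it did without parent 2 (adjusted p = 0.0304, direction down). Within it the core antenna genes pufA (19682 ± 241 to 9724 ± 434 CPM; -1.02 ± 0.07) and pufB (40941 ± 6563 to 20789 ± 158 CPM; -0.98 ± 0.11) and the carotenoid gene crtE (-0.95 ± 0.07) fell most among the genes that passed. Of the 50 tags of the locus range of this cluster, 20 had no gene in the table.

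Further lists, of carbon metabolism, protein folding and respiration, moved down on balance by fry, some with members that rose. All 6 genes of benzoate degradation in the table fell (median -0.86; fry adjusted p = 1.82e-04), from low levels, with badA at 41.4 to 20.6 CPM (log2 -1.01 ± 0.08 SE), hbaG (-0.95 ± 0.13) and hbaE (-0.94 ± 0.11). Of the 20 tags of that locus range, 14 had no gene in the table, so the pathway as a whole was not measured. Of 10 chaperone and protease genes, 7 fell and 3 rose (median -0.48; fry adjusted p = 0.0059, direction down). The small heat-shock protein gene hspD fell from 8191 ± 104 to 779 ± 1.62 CPM (SD, n = 2; -3.39 ± 0.07), groES2 (-1.92 ± 0.07) and clpB (-1.91 ± 0.07) fell too, whereas clpA, for an ATPase of the Clp protease, rose from 3586 ± 204 to 12602 ± 218 CPM (1.81 ± 0.08). Of 13 genes of the citric acid cycle and glyoxylate shunt, 10 fell, 2 rose and 1 did not pass (median -0.43; fry adjusted p = 0.031, direction down). acnA, for aconitase (-1.69 ± 0.09), sdhB (-0.88 ± 0.09) and fumA (-0.87 ± 0.08) fell, while the most abundant member, the isocitrate lyase gene aceA, rose from 10565 to 15349 CPM (0.54 ± 0.07). The list for the high-affinity cbb3 oxidase held 3 genes, of which 2 fell and 1 did not pass (median -0.19; fry adjusted p = 0.00607, direction down). fixG fell (-1.79 ± 0.07), and the abundant fixN changed by -0.19 ± 0.07, a call that ended in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment without suppressor 3 (adjusted p = 0.297), without suppressor 4 (adjusted p = 0.289), without the 10 most abundant genes (adjusted p = 0.0638) and with a scaling centred on the empty range (adjusted p = 0.101). Counts adjusted over the list alone were the same for these 4 lists. None of the 4 passed with an estimated correlation (adjusted p = 0.566 for benzoate degradation, 0.65 for chaperones, and 0.697 for the citric acid cycle and the oxidase), nor by fry without suppressor 3 (adjusted p = 0.129 to 0.205) or suppressor 4 (0.119 to 0.206).

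Genes of iron-sulfur cluster assembly and of the vanadium nitrogenase locus mostly rose, while genes of nitrogen regulation moved both ways. Of 22 genes of nitrogen regulation and ammonium assimilation, 14 rose, 7 fell and 1 did not pass (median 0.53; fry adjusted p = 0.00607, direction up). The main glutamine synthetase gene by abundance, glnA, rose from 10860 ± 160 to 16930 ± 200 CPM (SD, n = 2; log2 0.64 ± 0.07 SE), and glnAIII rose by 1.29 ± 0.08, whereas glnK1 (-1.48 ± 0.08) and glnA4 (-1.41 ± 0.07) fell. Of the suf operon and hesB, which serve iron-sulfur cluster assembly, 5 of 5 rose (median 0.92; fry adjusted p = 0.00607), with sufC at 247 to 630 CPM (1.35 ± 0.07), sufD (1.09 ± 0.07), sufS (0.92 ± 0.07) and the most abundant, sufB (0.57 ± 0.07). At the vanadium nitrogenase locus 8 of 9 genes rose and 1 fell (median 1.02; fry adjusted p = 0.00422). Levels there were low, with vnfA, the regulator, at 34.3 to 86.4 CPM (1.33 ± 0.08), RPA1370 (1.32 ± 0.14) and RPA1375 (1.29 ± 0.11). The counts were the same adjusted over the list alone. With an estimated correlation the 3 lists had adjusted p = 0.609, 0.566 and 0.566, and by fry 0.129 to 0.205 without suppressor 3 and 0.13 to 0.157 without suppressor 4.

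Calvin cycle genes, motility genes and a list drawn up for polyhydroxyalkanoate storage moved up on balance by fry, with smaller changes. Of 14 Calvin cycle genes 10 rose, 3 fell and 1 did not pass (median 0.34; fry adjusted p = 0.00422), among them cbbX (15.1 ± 0.0514 to 42.8 ± 2.88 CPM, SD, n = 2), cbbY (log2 0.88 ± 0.11 SE), the form II rubisco gene cbbM (891 ± 98.8 to 1389 ± 1.63 CPM; 0.64 ± 0.09) and cbbT1 (0.45 ± 0.08). Of 24 flagellar and chemotaxis genes 20 rose, 3 fell and 1 did not pass (median 0.39; fry adjusted p = 0.0307), led by cheY3 (0.79 ± 0.12), fliG (0.77 ± 0.13) and cheW3 (0.70 ± 0.06). Its most abundant gene, cheA2 (0.30 ± 0.07), was not called without suppressor 3 (adjusted p = 0.108) or suppressor 4 (adjusted p = 0.112) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All 6 pha and phb genes of the storage list rose (median 0.44; fry adjusted p = 0.0214). However, phaF (0.77 ± 0.13), phaG (0.58 ± 0.16), phaC (RPA2790; 0.56 ± 0.20) and phaD bear symbols that are also used for a potassium efflux system. Their tags lie between RPA2790 and RPA2794, and this phaC (342 bp) is short beside phbC (1806 bp). The list thus does not show how storage genes moved as a group. The change of phaC was 0.24 without suppressor 3 (adjusted p = 0.222, edgeR quasi-likelihood test with Benjamini-Hochberg), the synthase gene phbC (373 to 450 CPM; 0.27 ± 0.07) was not called without suppressor 3 (adjusted p = 0.1) or suppressor 4 (adjusted p = 0.118), and phaG was not called without parent 1 (adjusted p = 0.0546) or with DESeq2 (adjusted p = 0.0556). Counts adjusted over the list alone were the same. With an estimated correlation the adjusted p was 0.566 for the Calvin cycle, 0.697 for motility and 0.65 for the storage list. Without suppressor 3 the Calvin cycle list alone among all lists still passed fry, and motility and storage had adjusted p = 0.216 and 0.205. Without suppressor 4 the 3 lists had 0.119, 0.224 and 0.163.

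Other lists gave no call by fry. The 7 genes of molybdate transport and molybdenum cofactor synthesis rose, with a median of 0.72 (fry adjusted p = 0.0879), a test that passed without parent 1 (adjusted p = 0.0265) and without parent 2 (adjusted p = 0.0384). The call of its most abundant gene, modA (log2 0.31 ± 0.09 SE), ended in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment without suppressor 3 (adjusted p = 0.11) and suppressor 4 (adjusted p = 0.108), and its change was 0.20 without parent 2. Ribosomal protein genes divided evenly, with 16 rises, 16 falls and 1 that did not pass among 33 (median 0.10, mean -0.17; fry adjusted p = 0.42, direction up), and the test passed downward without parent 1 (adjusted p = 0.0265). Cobalamin synthesis had 10 rises, 4 falls and 1 gene that did not pass among 15 (median 0.42; fry adjusted p = 0.109), and passed upward without parent 2 (adjusted p = 0.032). The 3 ATP synthase genes gave 1 rise and 2 falls (median -0.26; fry adjusted p = 0.842, direction up) and passed downward without parent 1 (adjusted p = 0.0265). Both falls, atpA (-0.35 ± 0.09) and atpD (-0.26 ± 0.10), lost their call by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment without suppressor 3 (adjusted p = 0.102 and 0.184) and suppressor 4 (0.0879 and 0.221), and were -0.22 and -0.11 without parent 2. atpD, at -0.40 without parent 1, was not called either with limma-voom (adjusted p = 0.0504), without the 10 most abundant genes (0.0519) or with the centred scaling (0.0895). The FixABCX list, with 2 rises and 2 falls, 1 of them the deleted fixC (median -0.03, mean -2.43), had a fry adjusted p of 0.392. Lists with 1 or 2 members were not tested as lists: anfA, of the iron-only nitrogenase, and pimD, of pimelate degradation, changed by 0.27 ± 0.08 and 0.23 ± 0.07 on the log2 scale, calls by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment that ended without suppressor 3 (adjusted p = 0.121 and 0.164) and without suppressor 4 (0.0514 and 0.0681). With DESeq2 they ended too (adjusted p = 0.114 and 0.19), and that of pimD with RLE scaling (adjusted p = 0.0769). Of the catalase genes katG fell from 11451 ± 1305 to 7077 ± 113 CPM (SD, n = 2; log2 -0.69 ± 0.09 SE) and katE rose (0.67 ± 0.09). Adjusted over the list alone, all counts in these lists were the same. Among the falls of ribosomal protein genes, rplB, rplW, rplD, rplC and rpsJ were neighbours. They belong to a run, RPA3247 to RPA3253, with a median log2 fold change of -1.08.

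**Figure D4:**
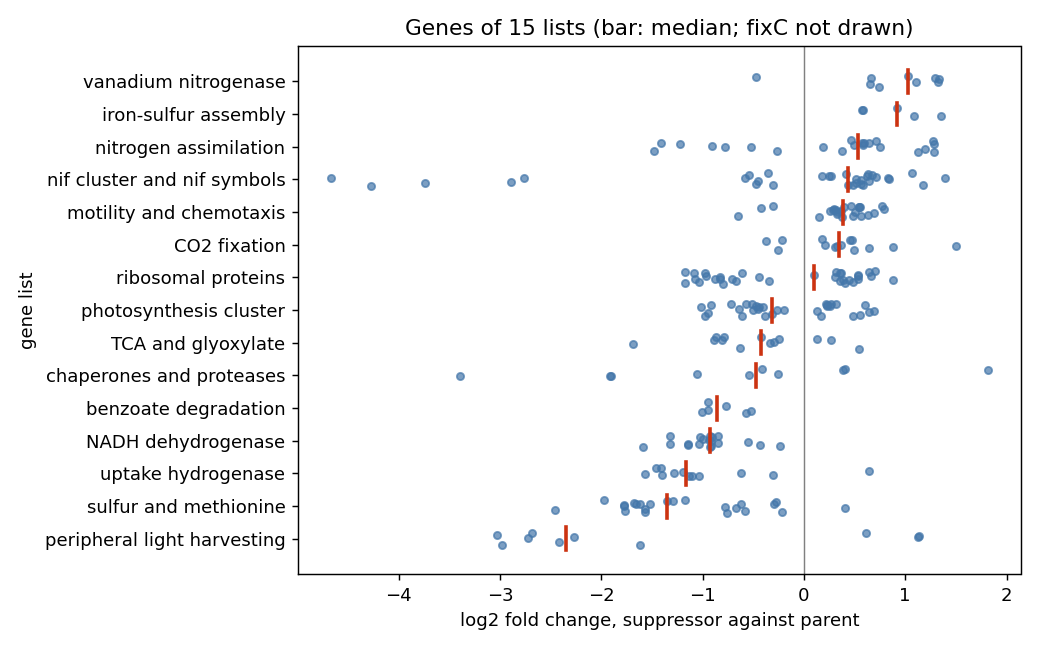
Log2 fold change (suppressor against parent) of each gene in 15 lists, with a red bar at the median of the list and fixC not drawn. The peripheral light-harvesting list has the lowest median, -2.35, and the vanadium nitrogenase list the highest, 1.02.

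As shares of the counts in the table, genes of the photosynthesis cluster and LH2 together took 17.04% and 14.33% in the parent libraries and 8.16% and 8.14% in the suppressor libraries, or 15.7% ± 1.92 against 8.15% ± 0.01 (SD, n = 2). Genes of the nif cluster took 2.29% ± 0.20 and 2.71% ± 0.01, or 1.94% ± 0.18 and 2.71% ± 0.01 without the deleted fixC. The stable RNAs rnpB and ffs, whose share can move with RNA quality and rRNA depletion, took 1.85% ± 0.12 in the parent and 1.58% ± 0.04 in the suppressor. No test was made on these shares.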

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

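The scaling centred on the empty range, the values multiplied by length, the values divided by 2 and the removal of the 5 stretches were tests chosen only after the results were seen. No gene called in the report changed sign under any alternative run. The lack of overlap between the strains and the empty range around 0 nearly fixed that outcome, so it does not support the calls. The count of 2862 called genes ranged from 2331 (adjusted p of 0.01) to 2912 (scaling centred on the empty range) with all libraries and no fold threshold, DESeq2 giving 2594 and limma-voom 2865. The share of rises among calls was 43.9% with DESeq2 and 52.3% with the centred scaling, against 49.2%. An absolute log2 fold change of at least 1 left 681 genes, 343 that rose and 338 that fell, by construction. Leaving out a library gave 2195 to 2929 called genes, 1069 to 1481 rises and 1126 to 1448 falls, and log2 fold changes of -12.351 to -9.488 for fixC, -0.756 to -0.382 for fixA, 0.47 to 0.549 for fixB and 0.653 to 0.759 for fixX, with the lone library of a strain assumed to vary like the other strain.

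List calls depended on the test. fry called 14 of 21 lists, 6 up and 8 down. Since every gene of the table separates the strains, these calls tell which direction prevailed, not that a list stood out. camera called 7 with a preset correlation (3 up, 4 down: iron-sulfur assembly, motility and the vanadium nitrogenase up, benzoate degradation, NADH dehydrogenase, sulfur assimilation and uptake hydrogenase down) and 0 with an estimated correlation (0 up, 0 down, and 0 at an unadjusted p under 0.05). With an estimated correlation, camera did not call even the 5 stretches picked for their large changes (adjusted p = 0.3464 to 0.3955). Its lack of calls therefore cannot decide whether a list moved. Leaving out a library gave 0 to 18 lists, 0 to 8 up and 0 to 10 down. Of these, 1 list was called without suppressor 3, 0 without suppressor 4, 17 without parent 1 and 18 without parent 2. The number of libraries alone does not set these counts, since each leaves out 1. Without a suppressor library the spread rests on the parent pair, which differed more (chi-square per degree of freedom 72.1) than the suppressor pair (4.0). With stable RNAs left out of the total, the suppressor's mean shares were 2.76% for the nif cluster and 8.28% for photosynthesis genes. No paired analysis was possible because the sample numbers 1 to 4 do not repeat between the groups. Lists without product names were identical to those used, since the table holds none. A filter on normalized values and thresholds on an authors' comparison were not run, as the table holds neither. The smallest departure of a gene from the middle of the empty range was 0.232 in the lowest of 4 equal groups by abundance (median 21.7 CPM) and 0.132 in the highest (462.6 CPM).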

Other observations

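The 5 chromosome stretches, the lists of gene transfer agent, denitrification and phosphate genes, the runs of neighbours and the tests of copy number and of a lost region were chosen only after the results were seen. Across the 3 stretches that rose, all members in the table rose: 16 of 16 in RPA2114 to RPA2129 (median log2 3.33, summed CPM from 3964 to 50107), 8 of 8 in RPA2306 to RPA2313 (2.66, 475 to 4282) and 19 of 19 in RPA2376 to RPA2395 (2.76, 5141 to 45165), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Their few symbols include exbB3 (3.24 ± 0.08 SE) and exbD3 (3.36 ± 0.10), which energise TonB-dependent uptake, and fecR4 (2.37 ± 0.07), a regulator of iron uptake. The other symbols there are nrtC1, cynS, prpC and prpB. Across the 2 stretches that fell, 19 of 19 in RPA2346 to RPA2364 (-3.72, 8847 to 1177) and 28 of 28 in RPA2608 to RPA2636 (-2.46, 4493 to 635) fell, with the sulfur genes metY, metC and ssuB beside the nifH and nifB relatives.

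Gene transfer agent genes, which package host DNA into phage-like particles, rose in 10 of 10 cases (median 0.92; fry adjusted p = 0.00322 over the lists chosen afterwards without the stretches, adjusted p = 0.26 with an estimated correlation), although GTA orfg10.1 (RPA1901) was not called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment without parent 2 (adjusted p = 0.0621) or suppressor 4 (adjusted p = 0.106). Genes of denitrification gave 2 rises and 8 falls (median -0.49; fry adjusted p = 0.0737), of which norC (-0.89 ± 0.30 SE) was at -1.39 without suppressor 3 and at -0.55 and not called without suppressor 4 (adjusted p = 0.09, edgeR quasi-likelihood test with Benjamini-Hochberg). For phosphate and phosphonate genes, with 6 rises and 2 falls (median 0.32), the fry adjusted p was 0.0466 with the 5 stretches among the lists tested and 0.0524 without them, and adjusted p = 0.462 with an estimated correlation. The fall of phnE2 was not called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment without parent 2 (adjusted p = 0.124) or suppressor 3 (adjusted p = 0.0573). Among runs of at least 5 neighbours that were called with an absolute log2 fold change of at least 1 in 1 direction, the largest medians outside the 5 stretches were those of RPA4162 to RPA4166, 5 genes without symbols that rose (2.55), and of RPA1362 to RPA1367, 6 genes with soxZ1 and soxY1 that fell (-2.38).

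The rise of the 3 stretches was set against technical and genetic explanations. A bias with gene length shared with the other genes was argued against by the size of the trend. Fitted on genes outside the stretches, it spanned only -0.08 to 0.52 on the log2 scale. Removing so small a trend could hardly move the median of the stretches, which was 3.24 after and 3.11 before. More copies of the stretches stay open: the SD of log2 fold change over their genes was at least 5.43 times the mean standard error, but genes outside the stretches varied as much (9.37 times), so the spread does not argue against a common fold on top of other changes. A change in regulation in the suppressor strain may lie behind the rise, through the loss of fixC or through the suppressor mutation. Without the unsuppressed deletion strain, these cannot be told apart. A difference in how the 2 strains were cultured may lie behind it too, since nothing in the labels separates strain from culture.

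The fall of the other 2 stretches was weighed in the same way. The same trend with gene length, of -0.08 to 0.52, was far too small for their median of -2.90 (-2.72 after its removal). This argues against a length bias shared with the other genes. Loss of the stretches from the genome was argued against too: 0 of their genes had at most 1% of the parent level left, and the lowest had 3.72%, where fixC had 0.019% and 0.139%. Lower transcription in the suppressor may account for the fall, and culture remains untested here as well. Here too, the loss of fixC and the suppressor mutation cannot be told apart.

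The empty range of log2 fold changes around 0 may come from a step that kept genes by a test of the difference. Such a step would widen the range at low counts, whereas a fixed fold threshold would not, and the smallest departure from the middle of the range was 1.76 times as large in the lowest of 4 equal groups by abundance as in the highest. No biological explanation was tested for this pattern.

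A hypothesis raised by the stretches that rose was that iron uptake genes elsewhere rose too. The list of 20 genes was drawn up by symbol after the stretches had been seen and before the values of its 17 genes outside them were. Of these, 14 rose and 3 fell, with a median of 1.14, which lay at percentile 100 of 10000 random lists of 17 genes from the table, whose 95th percentile was 0.41. pchR (1.88 ± 0.07 SE), hasR (1.43 ± 0.08) and fiu (1039 to 2515 CPM; 1.28 ± 0.07) rose, and those that fell were exbB1, fecR3 and bfr, the gene of the iron store bacterioferritin (1198 to 531 CPM; -1.18 ± 0.14). Random lists take no account of correlation between genes, several of which sit side by side. The 17 genes moved up by fry (adjusted p = 0.00146) and by camera with a preset correlation (adjusted p = 0.00582). With an estimated correlation camera gave adjusted p = 0.26, but that form did not call the stretches either and cannot decide. The list was prompted by the stretches and every gene of the table separates the strains, so a wider iron response in the suppressor stays a hypothesis.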
